A study of Dracunculus medinensis with 11 samples.

How the data were processed

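RNA was extracted from 5 pools of counted L1 and from tissue of 2 adult female worms recovered from 1 ferret, and poly(A) RNA libraries were made with a stranded TruSeq kit, per the labels. The sample labels give the material as the whole organism. The authors deposited 1 table of FPKM per gene and library, which holds 10261 genes and 11 libraries. Reads were trimmed, inspected, aligned and quantified with software that includes cutadapt, FastQC, HISAT2 and StringTie, per the submitters' processing notes, which list these names without versions. The genome build and the annotation are not given in the sources used here. No genome or annotation was used here, so that no coordinates are given.

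FPKM values are scaled to a fixed number of fragments per library, so a gene that takes most of the fragments lowers the values of all others. Values had 2 decimals, and ratios of low values between libraries did not fall on the steps that whole reads would leave. Ratios were binned at a width of 0.02 on the log2 scale for each pair of libraries. The fullest bin of any pair held 2.52% of the genes compared in that pair, which were drawn from 1393 low genes. Depth is therefore unknown, no test on counts was run, and no counting interval is given. A value of 0 in such a table can be a failed estimate, and genes are described as listed at 0.

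Libraries were grouped by stage and worm from their titles, where the worm number pairs adults with larvae: L1 of worm 1 (n = 2), L1 of worm 2 (n = 3), adult worm 1 (n = 3) and adult worm 2 (n = 3). The tests, alternatives and the rule for the genes to name were fixed before the data were examined. Genes at 1 FPKM or more in at least 2 libraries were tested (8388 genes). limma 3.58.1 in R 4.3.3 was fitted to log2(FPKM + 1) with 4 group means and moderated variances with trend and robust settings, leaving 7 residual degrees of freedom before moderation. Contrasts were the mean of the within-worm stage differences (L1 minus adult), the stage difference in each worm, the difference between these (worm 2 minus worm 1), and worm 2 minus worm 1 in adults and in L1. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05 and an absolute log2 change of 1 or more. Library measures were compared by two-sided exact permutation tests over all 462 splits of 11 libraries into 5 and 6, adjusted over 9 measures. Tables, tests and figures also used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.

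The model was tested on simulated data for the stage contrast over 8388 genes. It called 34.3% of genes changed 2-fold, 94.0% of those changed 4-fold and 100% of those changed 8-fold, and it called 7 of 8188 unchanged genes. Noise was independent between genes, with the same SD in all groups and no difference between worms. The changed genes were a small part of all genes, and none had the lowest levels. These rates therefore do not carry over to low genes, to unequal spread between groups or to differences between animals.

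Before the data were examined, 48 gene lists (34 by name and 14 by protein motif) were fixed. The table pairs no IDs with names beyond the 2 labels, so 0 lists had a matching member and no list was tested. The rule for named genes then gave, per comparison, up to 2 IDs with the largest rise and 2 with the largest fall among called genes, those of the stage comparison changing the same way in both worms. The 2 labelled genes and the most abundant gene were added after the table was seen, in place of the most abundant genes of each stage that the rule had asked for.

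Alternatives were other pseudocounts (0.1 and 5), no filter and a filter of 5 FPKM, rescaling to equal totals, quantile normalization, median-of-ratios scaling, limma without trend and robust settings, a replicate block, other treatments of worm, fits to part of the libraries, and each library left out in turn. Leaving out the most abundant gene was added after seeing the data. When an omission left a group with 1 library, that library was assumed to vary like the other groups.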

Results

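Poly(A)-selected RNA of Dracunculus medinensis, the Guinea worm, was sequenced from first-stage larvae (L1) and from adult females. Both adult worms came from under the skin of 1 ferret that had eaten copepods carrying infective larvae, and the L1 were taken from the same 2 worms. The L1 libraries were 2 pools from worm 1 (1100 and 1600 larvae) and 3 pools from worm 2 (1100, 1600 and 4800 larvae), and each adult worm gave 3 libraries, so that 5 L1 libraries were set against 6 adult libraries. The table held 10261 genes as FPKM (fragments mapped to a gene, scaled by its length and by the mapped fragments of the library), with library totals from 1198198 to 1469460 FPKM. Read depth is unknown, because FPKM does not carry it. Of the gene IDs, 10259 were not paired with a name, and the remaining 2 carried the labels DUF148 and TRX. The animal is the biological unit and there were 2, so p-values here mainly measure the spread between libraries of the same worms and their larvae. Fits to 1 mean per worm and stage instead use the spread between the worms, which rests on 2 animals.

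A single gene, gene:DME_0000035401, held most of the summed FPKM in every library. FPKM is divided by gene length, which is not given in the sources used here, so this is not its share of reads. It held 76.8% ± 2.74 of total FPKM in L1 (SD, n = 5) and 60.5% ± 5.70 in adults (SD, n = 6), and every L1 library lay above every adult library (two-sided exact permutation test, p = 0.00433, Benjamini-Hochberg adjusted p = 0.00649 over 9 library measures). The adult share was 65.6% in worm 1 and 55.5% in worm 2. On the log2(FPKM + 1) scale its level was higher in L1 by 0.57 (SE 0.13, limma adjusted p = 0.00131), which is under the 2-fold threshold used for calls. The change was 0.35 with libraries rescaled to the same total (limma adjusted p = 0.0389) and 0 by construction under quantile normalization, and with 1 mean per worm and stage the limma adjusted p was 0.391 with worm as a block and 0.184 without. The identity of this gene, and whether it is a messenger RNA or a structural RNA left in the table, is not given in the sources used here, so shares of total FPKM need not be shares of messenger RNA.

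L1 libraries held more detected genes than adult libraries. At 1 FPKM or more, 6966 ± 323 genes were detected in L1 (SD, n = 5) and 6046 ± 138 in adults (SD, n = 6), a difference of 920 genes (two-sided exact permutation test, p = 0.00433, adjusted p = 0.00649), where 0.00433 is the smallest p these group sizes allow. Within worm 1 the difference was 993 genes (exact p = 0.2) and within worm 2 it was 864 genes (exact p = 0.1), each the smallest p that its number of libraries allows. The excess lay among genes of low level, since at 5 FPKM or more the counts were 3687 ± 464 in L1 (SD, n = 5) and 3542 ± 146 in adults (SD, n = 6; exact permutation p = 0.615). At that level L1 minus adult was −26.8 genes in worm 1 and 276 in worm 2. Detection of low genes depends on read depth, which is unknown, so a difference in depth between the stages was not excluded as the source. Across the L1 pools, 7148 and 6886 genes were detected in the worm 1 pools of 1100 and 1600 larvae. In worm 2, 7427, 6629 and 6740 genes were detected in the pools of 1100, 1600 and 4800 larvae. The 100 most abundant genes held 93.5% ± 1.85 of FPKM in L1 (SD, n = 5) and 88.9% ± 1.11 in adults (SD, n = 6; exact permutation p = 0.00866, adjusted p = 0.0111). Without gene:DME_0000035401, a setting chosen after seeing the data, these shares were 72.4% and 71.3% (exact permutation p = 0.710), with L1 above adults by 10.1 percentage points in worm 1 and a difference of −6.53 points in worm 2.

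Libraries separated by stage first and, among adults, by worm. The leading principal component held 67.4% of the variance and parted L1 from adults, and the next held 14% and parted adult worm 1 from adult worm 2, with all L1 libraries between them. Across genes, which are not independent replicates, Pearson's r of log2(FPKM + 1) was 0.972 to 0.978 between adult libraries of the same worm and 0.874 to 0.884 between adult libraries of different worms. Between L1 pools r was 0.918 to 0.932 within a worm and 0.863 to 0.929 between worms, and between stages it was 0.579 to 0.641. The median within-group SD per gene was 0.23 in adult worm 1, 0.24 in adult worm 2, 0.31 in L1 of worm 1 and 0.48 in L1 of worm 2 on the log2 scale.

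**Figure D1:**
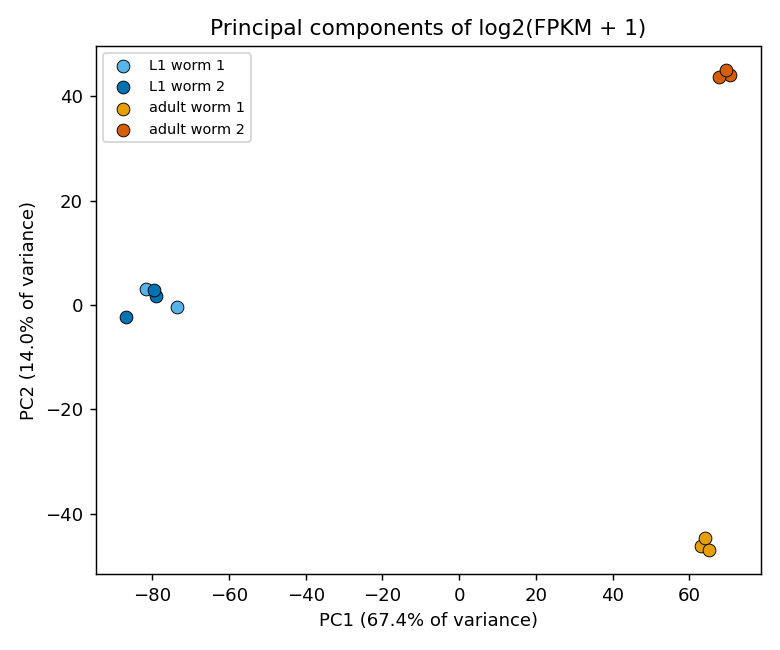
Each point is 1 library, placed by its scores on the leading principal components of log2(FPKM + 1), with the percent of variance on each axis. The horizontal axis (67.4% of the variance) parts the 5 L1 libraries from the 6 adult libraries, and the vertical axis (14%) parts the adult libraries of worm 1 from those of worm 2.

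The stage comparison asked which genes differ between L1 and adult females, as the title of the series states. The genes that differed most were higher in adults. gene:DME_0001040301 stood at 15.3 ± 2.59 FPKM in L1 (SD, n = 5), 11790 ± 1094 in adult worm 1 and 30139 ± 3813 in adult worm 2 (SD, n = 3 each), a log2 change of −10.18 in L1 against adults (SE 0.17, limma adjusted p = 1.10e-15). gene:DME_0000956601 stood at 4.50 ± 1.03 FPKM in L1, 1913 ± 271 in adult worm 1 and 9278 ± 2232 in adult worm 2 (log2 change −9.61, SE 0.19, limma adjusted p = 8.64e-15). In the other direction, gene:DME_0000223601 was at 1407 ± 774 FPKM in L1 against 27.4 ± 4.13 in adult worm 1 and 4.55 ± 1.27 in adult worm 2 (log2 change 6.56, SE 0.22, limma adjusted p = 1.11e-12). gene:DME_0001083501 was at 232 ± 53.7 FPKM in L1 and 2.16 ± 1.29 over the adult libraries (SD, n = 6; log2 change 6.30, SE 0.23, limma adjusted p = 2.84e-12). Both L1-rich genes were among 26 L1-rich genes that lay under 3% of their L1 level in adults, at a median of 2.41% in worm 1 and 0.833% in worm 2.

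Of 8388 genes tested, 3641 were called (limma adjusted p under 0.05 and a change of at least 2-fold), 1978 higher in L1 and 1663 higher in adults. The larger the change, the more the calls lay on the adult side. At 4-fold or more 506 genes were higher in L1 and 765 in adults, at 16-fold or more 81 and 180, and at 64-fold or more 4 and 45. Abundant genes showed the same lean, with 96 higher in L1 and 305 higher in adults among 500 genes whose mean reached 100 FPKM in either stage. These counts by size and level used FPKM as deposited, where FPKM outside gene:DME_0000035401 averaged 328052 in L1 and 479600 in adults. They were not recomputed with that gene left out. A floor in the adult libraries could also limit the size of L1-higher changes. Among 263 genes at 50 FPKM or more in every L1 library, the lowest share of the L1 level was 0.840% to 0.927% in adult worm 1. It was 0 to 0.270% in adult worm 2. Among 452 genes as high in every adult library, the lowest share of the adult level was 0 in each L1 library. Whether larval RNA in the females sets this floor was not settled. Of the 100 most abundant genes of adults, 77 were called higher in adults and 5 higher in L1, and of the 100 most abundant of L1, 48 were called higher in L1 and 13 higher in adults, with 35 genes on both lists. Each list was chosen by level in its own stage, so a lean toward that stage was built in. Every L1 library lay above every adult library for 1692 genes and below for 1307, together 35.8% of tested genes. Randomly assigned libraries would give 0.433%, but libraries of the same 2 worms are not independent. Of the separated genes, 60 were at 1 FPKM or more in every L1 library and listed at 0 in every adult library, with a median level of 3.73 FPKM. For another 27 of them the reverse held, with a median of 7.52 FPKM and a highest mean of 435 FPKM in adults. These fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Which direction held more calls depended on the setting. L1-higher calls were 54.3% with FPKM as deposited, where the median change over all tested genes was 0.26. The majority turned to adults when libraries were rescaled to the same total (1440 higher in L1, 1797 higher in adults, 44.5% L1-higher, median change 0.05) with a filter of 5 FPKM (45.0%) and with a pseudocount of 5 (38.7%). It also turned without L1 of worm 2, replicate 1, with 1766 genes higher in L1 and 1782 higher in adults (49.8%). L1-higher calls were 71.2% when gene:DME_0000035401 was left out and libraries were rescaled, a setting chosen after seeing the data that moved the median to 0.62. With 1 mean per worm and stage and no worm term, 2262 genes were called.

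The labelled genes were both higher in adults. gene:DME_0000113301 (DUF148), whose label is that of a protein domain family of unknown function, was at 367 ± 153 FPKM in L1 (SD, n = 5) and 5142 ± 1500 in adults (SD, n = 6), a log2 change of −3.89 (SE 0.21, limma adjusted p = 2.32e-10). It was lower in L1 of both worms, by log2 changes of −4.51 in worm 1 and −3.26 in worm 2. The difference between these (1.25, SE 0.42, limma adjusted p = 0.0596) and that between the adult worms (−0.76, SE 0.28, limma adjusted p = 0.0811) did not pass the test. Both passed under quantile normalization (limma adjusted p = 0.000265 and 5.44e-06) and with gene:DME_0000035401 left out (limma adjusted p = 0.00177 and 0.00117). The former also passed with a filter of 5 FPKM (limma adjusted p = 0.0438) and without L1 of worm 2, replicate 3 (limma adjusted p = 0.0194). It missed the call on fold size alone under median-of-ratios scaling (0.96, limma adjusted p = 0.0382) and without L1 of worm 2, replicate 1 (0.93, limma adjusted p = 0.0377). The adult difference of −0.76 had a limma adjusted p of 0.00206 with only the adult libraries, 0.00662 without L1 of worm 2, replicate 1, and 0.0482 without its replicate 3, where it missed the call on fold size alone. Over all alternatives the limma adjusted p ran from 0.000265 to 0.2118 for the difference of stage changes and from 5.44e-06 to 0.2335 for the adult worms. gene:DME_0000774101 (TRX), a label often used for thioredoxin, was listed at 0 in all 5 L1 libraries. It stood at 90.8 ± 4.92 FPKM in adult worm 1 and 1.62 ± 0.989 in adult worm 2 (SD, n = 3 each), so that its adult level came almost wholly from 1 animal. Its stage change was −3.91 (SE 0.23, limma adjusted p = 6.65e-10). That call was lost with 1 mean per worm and stage (limma adjusted p = 0.312 with worm as a block and 0.1435 without).

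**Figure D2:**
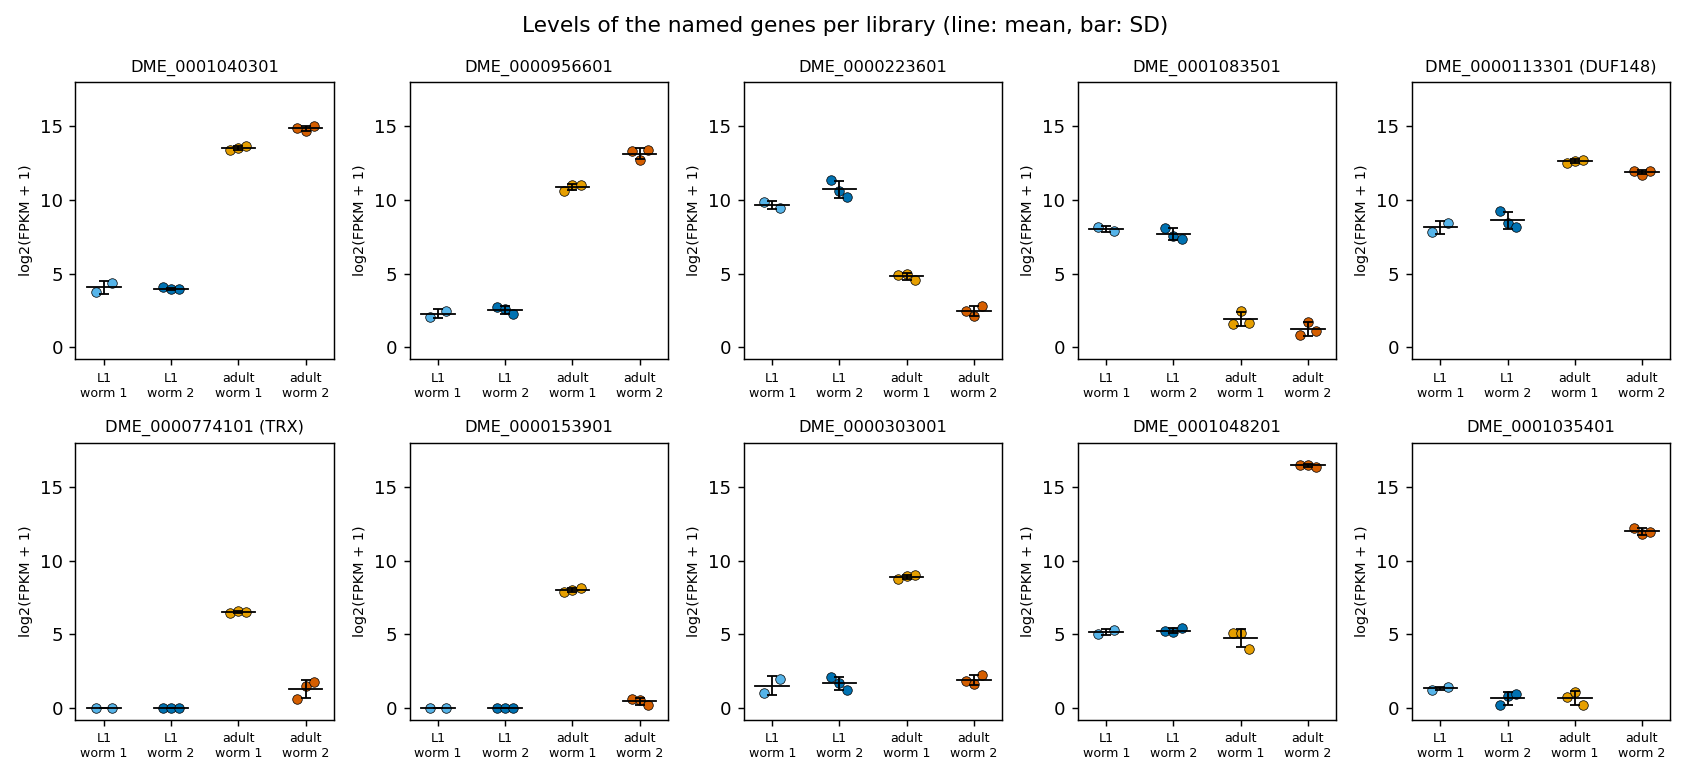
Levels of 10 genes named in the text as log2(FPKM + 1), with 1 point per library, a line at each group mean and a bar of 1 SD (n = 2 for L1 of worm 1 and n = 3 for each other group). gene:DME_0000774101 (TRX) is listed at 0 in all 5 L1 libraries and differs between the adult worms (90.8 and 1.62 FPKM), while gene:DME_0000113301 (DUF148) is higher in the adults of both worms.

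The stage change was then taken in each worm against the larvae whose titles carry the same worm number, the only label that ties the adult of worm 2 to its larvae. In worm 1, 3687 genes were called (1899 higher in L1, 1788 higher in the adult), and in worm 2, 3779 (2160 and 1619). For 1214 genes L1 was higher in both worms and for 1108 the adult was, where independent lists of these lengths would share 489.0 and 345.1, and 51 genes were called in opposite directions. Across genes, which are not independent, the stage change correlated between worms with r = 0.762. The test of the difference itself called 1167 genes, 713 with a more positive and 454 with a more negative L1-minus-adult change in worm 2. gene:DME_0000371701 was at 1746 ± 121 FPKM in adult worm 1 and 25.3 ± 3.22 in adult worm 2 (SD, n = 3 each), with L1 means of 23.7 and 65.0 FPKM in worms 1 and 2 (log2 difference of stage changes 7.52, SE 0.42, limma adjusted p = 7.17e-09). L1-higher calls were 51.5% in worm 1 and 57.2% in worm 2 as deposited, 42.3% and 49% with libraries rescaled to the same total, and 62.4% and 76.7% with gene:DME_0000035401 left out. A filter of 5 FPKM gave 42.4% and 49.6%, and a pseudocount of 5 gave 34.8% and 46.7%. Leaving out 1 library gave 45.5% in worm 1 without L1 replicate 1, 49.9% and 49.8% without adult replicates 1 and 2, and 49.5% in worm 2 without L1 replicate 1. With that gene left out the difference test called 1878 genes, 80.0% of them more positive in worm 2 against 61.1% as deposited. Median-of-ratios scaling gave 48.4%, and 740 genes were called without L1 of worm 1, replicate 2.

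**Figure D3:**
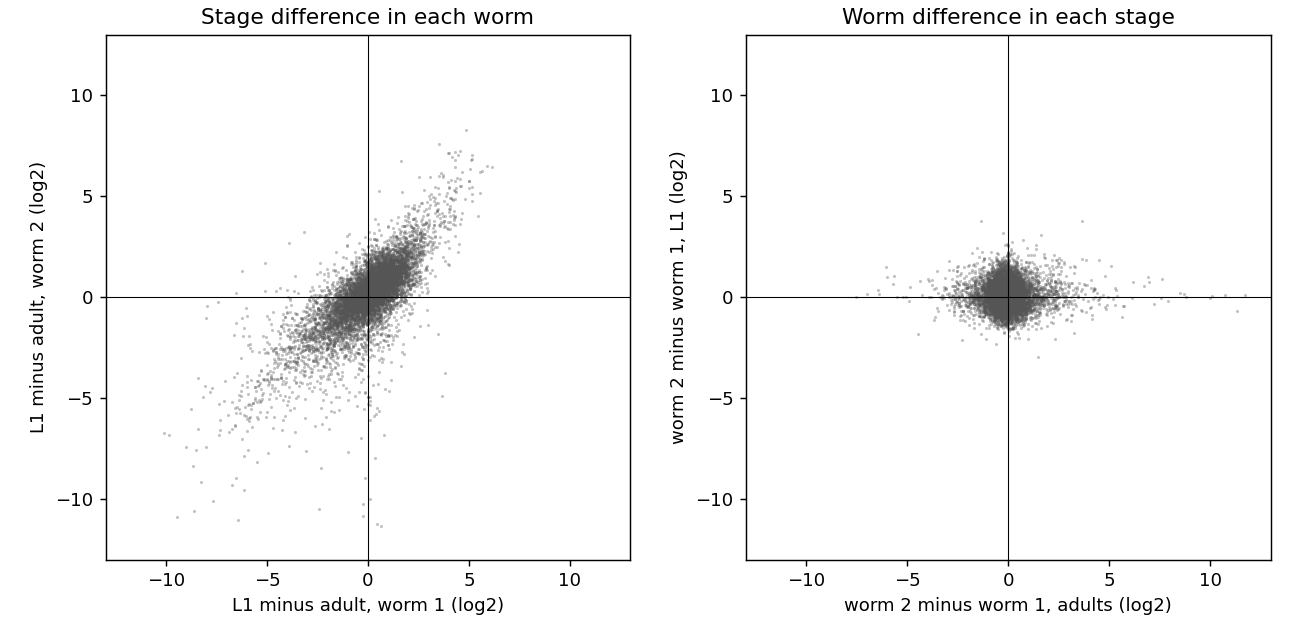
Each point is 1 of 8388 tested genes, plotted by log2 differences of log2(FPKM + 1). The left panel sets the L1-minus-adult change in worm 1 against that in worm 2 (r = 0.762 across genes), and the right panel sets worm 2 minus worm 1 in adults against the same difference in L1, where the adult axis holds the wider spread.

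The 2 adult worms differed at many genes, some by orders of magnitude. gene:DME_0001048201 stood at 91990 ± 5114 FPKM in adult worm 2 and 27.6 ± 10.8 in adult worm 1 (SD, n = 3 each; log2 change 11.73, SE 0.28, limma adjusted p = 1.43e-13), and L1 held 0.0399% of the adult worm 2 level. gene:DME_0001035401 stood at 4156 ± 675 FPKM in adult worm 2 and 0.653 ± 0.486 in adult worm 1 (log2 change 11.33, SE 0.29, limma adjusted p = 1.73e-13), with L1 at 0.0234% of that level. Higher in worm 1 were gene:DME_0000153901, at 256 ± 24.6 against 0.383 ± 0.221 FPKM and listed at 0 in every L1 library (log2 change −7.54, SE 0.26, limma adjusted p = 6.24e-12), and gene:DME_0000303001, at 482 ± 48.1 against 2.81 ± 0.856 FPKM (log2 change −7.01, SE 0.31, limma adjusted p = 1.53e-10). Where 1 worm lay near 0 FPKM, the size of the change depended on the pseudocount. With pseudocounts of 0.1 and 5 it was 12.69 and 9.52 for gene:DME_0001035401, and −9.18 and −5.59 for gene:DME_0000153901. gene:DME_0000774101 (TRX) was lower in worm 2 by a log2 change of −5.21 (SE 0.31, limma adjusted p = 5.12e-09). In all, 1210 genes were called, 581 higher in worm 2 and 629 higher in worm 1. Changes of 64-fold or more numbered 17 toward worm 2 and 6 toward worm 1. The libraries of the worms did not overlap for 38.1% of tested genes. Randomly assigned libraries would give 10%, but libraries of the same worm are not independent. Neither worm held a stable majority of calls: 48.0% were higher in worm 2 as deposited, 53.2% under quantile normalization, 56.7% under median-of-ratios scaling and 28.6% with gene:DME_0000035401 left out. The share was 52.2% without adult worm 2, replicate 2, and 50.1% without adult worm 1, replicate 3. This comparison is between 2 animals, each measured in 3 libraries, and what part of the worm each library came from is not given in the sources used here.

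L1 of the 2 worms gave fewer calls than the adult worms, and the number of calls depended on the setting. With 2 against 3 pools, against 3 libraries of each adult worm, the 2 counts are not equally sensitive. Under quantile normalization they were 912 for L1 and 1063 for adults, so fewer calls need not mean that the larvae were more alike. gene:DME_0000421301 was at 170 ± 154 FPKM in the worm 1 pools (SD, n = 2) and 1927 ± 878 in the worm 2 pools (SD, n = 3; log2 change 3.76, SE 0.49, limma adjusted p = 0.00602). gene:DME_0000812201 was at 5.40 ± 1.02 and 0.477 ± 0.443 FPKM (log2 change −2.15, SE 0.30, limma adjusted p = 0.00602), and at these low levels its change was −3.57 with a pseudocount of 0.1 and −0.92, under the 2-fold threshold, with a pseudocount of 5. With the spread shared over all libraries, 327 genes were called, 247 higher in L1 of worm 2 and 80 higher in L1 of worm 1. Quantile normalization called 912 genes, 311 of them shared with these, and a pseudocount of 0.1 called 208, with 185 shared. With only the L1 libraries limma called 0 genes, with 951 at an unadjusted p under 0.05, while the log2 changes of the named genes stayed at 3.76 and −2.15 (limma adjusted p = 0.0880 and 0.150). Likewise, without L1 of worm 1, replicate 2, it called 0, with 1122 at an unadjusted p under 0.05 and log2 changes of 2.67 and −1.99 for the named genes (limma adjusted p = 0.108 for each). Pools did not overlap for 29.1% of tested genes, where randomly assigned pools would give 20%, although pools of the same worm are not independent. The share higher in worm 2 was 75.5% as deposited, 52.2% under quantile normalization and 61.5% under median-of-ratios scaling. Without L1 of worm 2, replicate 1, the majority turned to worm 1, with 176 genes higher in L1 of worm 2 and 199 higher in L1 of worm 1 (46.9%). Of 71 genes called both here and between the adult worms, 43 went the same way in both and the rest in opposite directions. Of the 43, 37 were higher in worm 2, where independent lists would share 17.1, and 6 were higher in worm 1, where they would share 6.0.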

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

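The tests of explanations and the splits of the libraries in this part were chosen after the results they bear on were seen, except the test of larval RNA at a share of 0.927% as the source of the difference between the adult worms. Among 40 sets of L1 or adult values, 2 held a library far from the others, where chance gives about 2.0. The share of FPKM in the 100 most abundant genes was 90.3% in L1 of worm 2, replicate 1, below the other L1 libraries (gap over range 0.868). It was 91.0% in adult worm 2, replicate 2, above the other adult libraries (gap over range 0.670).

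The stage change differed between worms at 1167 genes by the test of the difference itself. Among named genes this difference, as the L1-minus-adult log2 change in worm 2 minus that in worm 1, was −1.44 for gene:DME_0001040301, −2.0 for gene:DME_0000956601 and 3.44 for gene:DME_0000223601. It was −12.01 for gene:DME_0001035401, −11.65 for gene:DME_0001048201 and 7.52 for gene:DME_0000371701. For gene:DME_0000774101 (TRX) and gene:DME_0000153901, which are listed at 0 in every L1 library, it was 5.21 and 7.54 and mirrors the difference between the adult worms.

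The stage contrast called 3641 genes, and 1 of 100 splits of the libraries within worms (of 200 possible), the real split, gave as many. The splits exchange repeat libraries and pools from the same 2 worms, so they set the stage difference against the spread between libraries only. Chance between animals could not be excluded with 2 worms. Of 99 other splits, 9 gave over 100 calls. The highest of the others gave 2822 genes. That split exchanged the stage of 10 of the 11 libraries and so was close to the mirror of the real one. Worm 2 alone gave 3779 genes and the highest other split 0, where 10 splits are too few for a share under 0.05.

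The adult worms differed at 1210 genes, against 0 in the highest other split, where 10 splits are too few for a share under 0.05. Scaling by the most abundant gene was argued against as the whole cause, since 1063 of the calls (87.9%) remained with that gene left out. Libraries were rescaled there by summed FPKM, which may not match that gene's share of reads. RNA with the profile of the L1 pools was too little to bring most of the differences at the shares considered. Of the differences, 99.7% exceeded 2 times what a larval share of 0.927% could bring. With a share of 1.91% (the lower 2% point of L1-rich genes in adult worm 1) 98.3% did. This rests on the limit set on the share, since at so low a share only genes far higher in L1 could fall short. RNA of embryos or larvae of another age was not tested. For a difference carried equally by the larvae, the 907 called genes at 1 FPKM or more in L1 were examined. The slope of the larval on the adult difference was 0.0235, and 51.6% of these genes went the same way in larvae and adults. Genes near 1 FPKM in L1 cannot hold a larval difference as large as the largest adult ones, so part of the low slope was built in. The slope therefore does not decide whether the larvae carried the difference. Its 95% bootstrap interval (0.00098 to 0.046) resampled genes, which are not independent. The interval may therefore be too narrow, and it leaves out the spread between animals. Differences in age, site in the ferret, tissue sampled or state of the animals may each contribute, were not tested, and cannot be separated with 1 worm on each side.

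Among genes at 50 FPKM or more in every L1 library, 26 lay under 3% of their L1 level in adults, at medians of 2.41% in worm 1 and 0.833% in worm 2. A candidate source is larval RNA inside the gravid female, which would give these genes 1 common ratio between the worms. Their SD around a common ratio of 0.342 was 2.35 times that expected from replicate libraries, and a first form of this test that ignored the pseudocount gave 2.62. With a median level of 1.91 FPKM in adult worm 2 these genes lie near the floor, so larval RNA and low expression by the adult cannot be told apart. The lowest share of the L1 level among 263 L1-rich genes is a rough limit on RNA with the profile of the L1 pools. It was 0.840% to 0.927% in the libraries of adult worm 1 (1.12% in their mean). In those of adult worm 2 it was 0, 0 and 0.270% (0.201% in their mean). The 26 genes are among these 263, so in each worm the lowest share lies below their median whatever the source. It therefore does not decide on larval RNA, and the values in worm 2 are close to 0.

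Models found almost only in adult worm 2 left a trace elsewhere. For 5 models at 500 FPKM or more in adult worm 2 and under 0.1% of that level in adult worm 1, the L1 share of the worm 2 level ran from 0.0234% to 0.0580%, a ratio of 2.47, over a 65.0-fold range of levels. The adult worm 1 share of the same models ran from 0.0157% to 0.0870%, a ratio of 5.53, with traces down to 0.297 FPKM, so reads crossing between libraries and low expression cannot be told apart near this floor. Of 17 models higher in adult worm 2 by 64-fold or more, 7 had an ID number over 10000 (41.2%), against 6.82% of tested genes, a limit chosen after these IDs were seen and so a description only. What these models encode, and whether they belong to the worm's own genome, was not tested.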

How the results depend on the processing

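Leaving out the most abundant gene was chosen after seeing the data, and the other settings before. Of 160 recomputed counts and library measures, 138 kept their side of the threshold or stayed within 1.5 times. A pseudocount of 5 gave 1746 genes by stage (38.7% higher in L1), 1826 in worm 1, 1932 in worm 2 and 664 between adult worms, as it shrinks low genes. With 1 mean per worm and stage, fewer samples entered and 2262 genes were called by stage without a worm term. L1 of the 2 worms gave 208 genes with a pseudocount of 0.1, 912 under quantile normalization, 667 under median-of-ratios scaling, 709 with the most abundant gene left out and 0 with only the L1 libraries, and the difference of stage changes gave 1878 with that gene left out. The cause was not tested. The difference in detected genes was 145.5 at 5 FPKM, and that in the share of the 100 most abundant genes was 1.13 points without the most abundant gene.

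With each library left out in turn, counts ran from 3548 to 3776 by stage, 3035 to 3757 in worm 1, 3611 to 3865 in worm 2, 740 to 1396 for the difference of stage changes, 996 to 1272 between adult worms and 0 to 707 between L1 of the worms. The difference in detected genes ran from 804.75 to 1004.25 and that in the share of the 100 most abundant genes from 4.40 to 5.50. The count of 740 came without L1 of worm 1, replicate 2, as did the 0. L1 of the worms gave 213 and 707 without replicates 2 and 3 of L1 of worm 2, 204, 187 and 182 without replicates 1, 2 and 3 of adult worm 1, and 192 and 186 without replicates 1 and 3 of adult worm 2. Among values of named genes, 440 kept a call and 13 lost it, while 105 stayed without a call and 6 gained it, and no call changed direction.

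Replicate numbers did not pair libraries, since deviations of 15 same-numbered pairs correlated at −0.106 to 0.0503. A replicate block gave 3657 genes by stage, 3680 in worm 1, 3791 in worm 2, 1169 for the difference of stage changes, 1231 between adult worms and 407 between L1 of the worms. Tests of gene lists were not run, as no list had a matching member. Depth is unknown, so its limits could not be set.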

Other observations

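The test in this part was chosen after the pattern was seen. Genes with consecutive ID numbers changed together between stages and, less closely, between worms. Across genes, which are not independent, the stage change correlated with that of the next ID at r = 0.241 (6738 pairs; permutation p = 0.0001, the smallest that 9999 permutations can give), with r = 0.0728 at a distance of 2 and 0.00379 at a distance of 3. For the next ID, r was 0.193 for the difference between the adult worms and 0.110 for that between L1 of the worms. Of 1382 adjacent pairs in which both genes were called by stage, 937 (67.8%) had the same direction, where the share of each direction gives 50.4%. If ID numbers follow position in the genome, neighbours may share regulation, or a single gene may be split over adjacent models. Neither was tested, because no annotation was used here.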
